A study of Caenorhabditis elegans with 36 samples.

How the data were processed

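The series measured which mRNAs associate with the microRNA-induced silencing complex (miRISC) in synchronized Caenorhabditis elegans. AIN-2 is a GW182-family protein of that complex, and a GFP-tagged AIN-2 was immunoprecipitated (IP) from whole-animal lysates with an anti-GFP antibody. Eggs were frozen directly, and larvae were collected after 4 (L1), 21 (L2), 30 (L3) and 42 (L4) hours on food at 20 °C. Total RNA (the input) was taken from the same lysate before the beads were added. Per the labels, every replicate of every stage was cultured and harvested independently. The 36 samples analysed here are the IP and the input of 18 lysates: 4 each of Egg, L1 and L3 and 3 each of L2 and L4. An IP from animals without the tag was not analysed here, so an mRNA held on the beads for other reasons cannot be told from one bound through AIN-2.

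Each sample is 1 dye channel of a spotted oligonucleotide array read in 2 colours. The IP carried Cy3 in 12 lysates and Cy5 in 6. The deposited values are in the unit intensity, on a linear scale and with background subtracted, and they were tested on the file: values below 0 occur, and in each column all values of 1 to 50 steps, 36.9% to 68.1% of the spots, lay within 0.05 of a whole number of steps, where chance gives 10%. Above 50 steps this was not tested as strictly. Each column mean lay between 0.975 and 1.13, so the deposited columns appear to have been scaled to a mean close to 1. The scanner, the image software and the scaling are not stated in the labels. The depth of an array is its signal over background. A spot was counted as above background when its value exceeded 3 times the noise of its column, taken from the values below 0. By this measure 31% to 70.4% of the spots of an IP and 51.3% to 71.4% of the spots of an input were above background. The number of arrays limits the precision of every value. From 0 to 166 spots of a sample lay over 65000 steps, near the top of the scanner scale, and 0 genes did so in every array of a group.

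Values of 0 or less (5.75% to 20.3% of the spots of a sample) were treated as missing, the rest were put on the log2 scale, and the 36 columns were quantile normalized. Of the 23232 spots, 17461 carried a gene symbol and 5771 did not. Probes of the same gene were averaged (880 genes had 2 or more probes), and unnamed probes stayed on their own. A gene or probe was tested when every stage had at least 2 lysates with both values. That left 15732 genes and probes, of which 12061 were named genes and 3671 were unnamed probes. Dim genes were not removed. The genome build of the probes is not named in the labels, so no coordinates are given. lin-14, lin-28, lin-41, daf-12 and ain-2 carried no named probe that could be used and were not analysed here.

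The IP was compared with the input within each lysate. limma 3.58.1 (R 4.3.3) was fitted to the IP minus input differences of the 18 lysates with a coefficient per stage and a dye term, which amounts to a lysate block, and variances were moderated with a trend on the mean level (12 residual degrees of freedom, 7.46 prior). The comparisons were the IP against the input at each stage, the mean of the 5 stages, the difference of the IP to input ratio between consecutive stages, and an F test of any difference between stages. Total RNA of consecutive stages was compared in a second limma fit to the 18 inputs with stage and dye (5.61 prior degrees of freedom). Calls are genes and probes with a Benjamini-Hochberg adjusted p under 0.05. Values are log2 differences, and the error given with ± is the standard error of the fit unless SD is written. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the figures.

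A total of 29 gene lists were tested for a shift against all other genes with camera (preset correlation 0.01) on lists of at least 5 measured members: known miRNA targets, heterochronic genes, miRISC and small RNA machinery, cytosolic ribosomal proteins, translation factors, proteasome subunits, mitochondrial oxidative phosphorylation, cuticle collagens, molting cycle genes, vitellogenins, major sperm proteins (with related sperm proteins), spermatogenesis genes, germ line and oocyte genes, embryonic specification genes, cell cycle and DNA replication, histones, body wall and pharyngeal muscle, neuronal genes, intestinal genes, epidermal genes, Ras MAP kinase and EGF signalling, insulin signalling, Wnt signalling, TGF-beta signalling, Notch signalling, nuclear hormone receptors, homeobox genes, heat shock proteins and chaperonins, and the ER secretory pathway. The adjusted p of a list is over the 29 lists of a comparison. Camera with a correlation estimated from the data, and fry, were run on the 8612 genes and probes with a value in all 36 samples.

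Genes are named by a rule. For each IP comparison these are the 10 highest and the 10 lowest called genes with the same sign in every lysate. For each comparison between stages they are the 5 highest and 5 lowest called genes. From each list they are the 2 highest and 2 lowest called members. Every measured member of the known miRNA targets, heterochronic genes and vitellogenins, and ain-1, alg-1, alg-2 and dcr-1, are also named. The groups, the comparisons and tests, the lists, this rule and most of the alternatives were chosen before the data were examined. Other genes are named only where the text says that they were chosen after their values were seen.

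The alternatives were the values as deposited, columns centred on their medians, a loess fit within each lysate (span 0.4), no dye term, no replicate block, a random lysate block, the replicate number as a replicate block across stages in place of the dye, leaving out the dimmest 0.25 of the genes, no variance trend, the brightest probe of a gene, complete genes only, each stage alone, and each of the 18 lysates left out in turn. Some alternatives were added after the data were seen: a floor at percentile 20 after linear quantile normalization, an offset of 0.1 before log2, the spelling of the input titles ("tot" in 12 lysates and "Tot" in 6) as a term or as a filter, and leaving out the 2 lysates with the lowest IP signal.

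The pairing of IP and input was checked on the complete genes. After the stage means were removed, the IP and the input of the same lysate correlated across genes with r from 0.287 to 0.621 (median 0.459), against a median of -0.194 for different lysates of a stage, and in 18 of 18 lysates the IP resembled its own input most. Genes are not independent replicates, so these r values only rank the pairs. The IP and the input of a lysate carried opposite dyes. If they were read on the same array, spot effects common to both channels would also correlate them. The check therefore cannot tell a shared lysate from a shared array. Removing the stage means by itself also makes the r of different lysates negative.

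The fits were tested on simulated data with the spread of these arrays, in which 200 of the genes and probes were changed. Of the changes of 2 on the log2 scale, 40.9% were recovered at Egg, 31.8% at L2, 16.7% for the ratio of L2 to L1 and 13.6% for total RNA of L4 against L3. Of the changes of 0.5, 0% were recovered in any comparison tried. There were at most 1 false calls per comparison. The adjusted threshold is stricter where fewer genes change. The simulated data gave 32 calls at Egg and 28 at L2, against 3502 and 2557 in the real data. The recovered shares therefore do not give the recovery of the IP against the input in the real data. A shift of -0.5 put into a list of 32 genes was estimated as -0.59 (camera adjusted p = 1.72e-20), with 0 of the 28 other lists called. The simulated genes were drawn independently of each other, so this does not test list calls where genes are correlated.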

Results

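The data are array intensities of mRNA in 36 samples from synchronized Caenorhabditis elegans at 5 stages. Each of 18 lysates gave an IP of the GFP-tagged miRISC protein AIN-2 and an input of total RNA. Egg, L1 and L3 had 4 lysates each, and L2 and L4 had 3 each. Between 31% and 70.4% of the spots were above background in an IP, and between 51.3% and 71.4% in an input. Replicate samples of a group correlated across genes with r from 0.735 to 0.965 in the IPs and from 0.826 to 0.979 in the inputs. Genes are not independent replicates in such a correlation. The number of arrays limits the precision of every value below. In total, 15732 genes and probes were tested, 12061 of them named genes.

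The comparison of the IP with the input asked which mRNAs were held with the silencing complex. Over the mean of the 5 stages, limma called 3014 genes and probes higher in the IP and 3946 lower, together 44.2% of those tested. Of these, 1626 were more than 2-fold higher and 2455 more than 2-fold lower. A total of 478 were higher at each of the 5 stages and 624 were lower at each, where independent calls would give 0.0989 and 0.247. The stages shared a fit with a common variance per gene and a common dye term, so their calls were not independent even without an effect. A further 118 were higher at one stage and lower at another. The balance of higher and lower calls depended on the scaling of the arrays. Of the calls at the mean, 43.3% were higher with quantile normalization, 51.6% with the values as deposited, 37.8% with columns centred on their medians and 48.6% with a loess fit within each lysate. The median of all genes and probes was -0.09 with quantile normalization, against 0.14 as deposited, -0.07 centred and -0.03 with loess. No list call at the mean of the stages held when the correlation between genes was estimated and p adjusted over the lists (lowest 0.0677), so the camera calls below depend on the fixed correlation. Below, a value written as p with an estimated correlation is unadjusted. A value introduced by "but" or "also" for that test is adjusted over the lists, so these 2 kinds cannot be ranked against each other. Fry tests the members of a list on their own and not their shift against other genes. By fry, 23 of the 29 lists had an adjusted p under 0.05 at the mean, and from 12 (L2) to 24 (L1) at a single stage. Directions of the called genes and lists named below held under these scalings except where a clause names one.

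The naming rule ranks only called genes with the same sign in every lysate. The counts of lysates given for the highest and lowest genes therefore follow from the rule. D2023.1 was highest, at 5.69 ± 0.154 (adjusted p = 8.97e-16, above 0 in 18 of 18 lysates). The zinc finger gene egl-46 followed at 5.43 ± 0.128 (adjusted p = 1e-16, 18 of 18 lysates). The potassium channel regulator sup-18 stood at 5.04 ± 0.147 (adjusted p = 2.71e-15, 18 of 18), and the glycosyltransferase gene bre-3 at 4.64 ± 0.107 (adjusted p = 1e-16, 18 of 18). ZK6.8, R05H11.2, Y42H9AR.5, npr-29, doxa-1 and lev-1 completed the 10 highest, between 4.25 and 4.58, each above 0 in every lysate with a value. At the other end, ribosomal protein mRNAs held 9 of the 10 lowest places under the same rule. rpl-37A was lowest at -3.32 ± 0.166 (adjusted p = 3.02e-12, below 0 in 18 of 18 lysates), and rplp-0 followed at -3.25. The other of the 10, rpoa-12, was at -3.08, but at -1.54 with an offset of 0.1 before log2.

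Published targets of microRNAs were compared as a fixed list of 9 measured genes. Their median was 1.10 above the input, and the list was above 0 in 18 of 18 lysates (camera adjusted p = 0.000538, but 0.0677 with an estimated correlation; median 0.57 with an offset of 0.1 before log2). Called higher were 5 of the 9 over all genes, and 6 adjusted over the list alone. hbl-1, a transcription factor of the heterochronic pathway that times larval fates, stood highest at 4.22 ± 0.126 (adjusted p = 3.25e-15, 18 of 18 lysates). The cell death activator egl-1 was at 1.88 ± 0.179 (adjusted p = 3.36e-08, 17 of 18). mef-2 was at 1.67 ± 0.111 (adjusted p = 1.61e-10, 18 of 18), and die-1 at 1.18 ± 0.138 (adjusted p = 5.82e-07, 14 of 18). unc-29 was at 1.10 ± 0.219 (adjusted p = 0.000394, 16 of 17 lysates, 0.57 with the offset). No call over all genes was made for pha-4 (0.30, adjusted p = 0.0549), let-60 (0.18, adjusted p = 0.162), cog-1 (-0.31, adjusted p = 0.733) or vav-1 (-0.05, adjusted p = 0.905).

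Heterochronic genes were also higher in the IP as a list (median 0.61, camera adjusted p = 0.021, but 0.148 with an estimated correlation, above 0 in 17 of 18 lysates; median 0.31 with lysates of one title spelling). Of 8 measured, 3 were called higher over all genes and 2 adjusted over the list alone. Beside hbl-1 these were nhr-25 at 1.55 ± 0.142 (adjusted p = 1.79e-08, 18 of 18 lysates) and mab-10. The mab-10 value of 0.62 (adjusted p = 0.0453, 14 of 18 lysates) fell short of a call in 18 of the alternatives, for example without Egg replicate 2 (0.39, adjusted p = 0.209), and was 1.00 with the brightest probe. blmp-1 (0.70, adjusted p = 0.175), lin-66 (0.60), lin-42 (0.20), lin-29 (0.13) and lin-46 (-0.12) were not called. The gene hbl-1 is in this list and among the known targets, so these 2 list calls are not separate evidence. Neither list was tested without hbl-1. lin-14, lin-28, lin-41 and daf-12 were not analysed here.

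The IP to input ratio of hbl-1 was lowest in eggs, where its input level was highest. The ratio was 1.42 at Egg, 3.96 at L1, 4.14 at L2, 5.61 at L3 and 5.97 at L4, and each was called. Between Egg and L1 the ratio rose by 2.54 ± 0.359 (adjusted p = 0.000648). That call ended with centred columns (2.74, adjusted p = 0.0638) and with lysates of one title spelling (1.97). In the input, hbl-1 fell by 3.38 between Egg and L1 (adjusted p = 1.14e-06), and all 4 L1 values lay below all 4 Egg values. Its level in the IP was 4.18 at Egg (SD 0.48, n = 4), 3.33 at L1 (SD 0.28, n = 4), 3.79 at L2 (SD 0.89, n = 3), 4.71 at L3 (SD 0.57, n = 4) and 4.10 at L4 (SD 0.86, n = 3). The IP levels of different stages were not tested against each other.

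**Figure D1:**
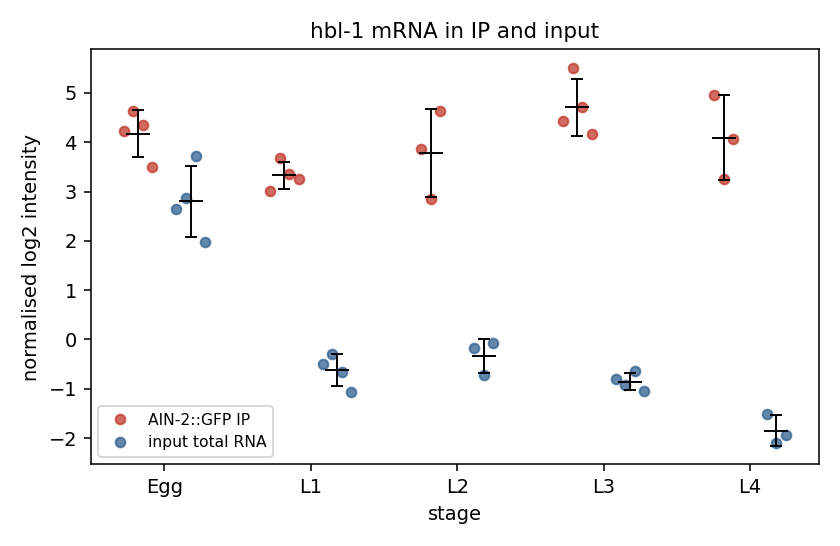
Level of hbl-1 (log2 normalized intensity, vertical axis) in the IP and in the input at each stage; points are samples, black marks the mean ± SD. The mean input level was 2.81 at Egg and -1.85 at L4, while the mean in the IP lay between 3.33 and 4.71 at every stage.

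Abundant mRNAs of protein synthesis, protein turnover and respiration were depleted from the IP. Cytosolic ribosomal proteins had a median of -2.52, below 0 in 18 of 18 lysates (camera adjusted p = 3.66e-34, p = 0.075 with an estimated correlation). Over all genes, 57 of 59 were called lower, and 58 adjusted over the list alone. The median by stage was -2.73 at Egg, -3.03 at L1, -1.99 at L2, -2.29 at L3 and -2.51 at L4. One member, rps-24, was called higher at 0.24 (adjusted p = 0.0398, 16 of 18 lysates), a call that ended under 15 alternatives, for example with centred columns (0.02). Mitochondrial oxidative phosphorylation genes had a median of -1.79, with 57 of 62 called lower and 58 adjusted over the list alone (camera adjusted p = 1.33e-26, but 0.0677 with an estimated correlation, 18 of 18 lysates). Proteasome subunits stood at -1.17, with 27 of 32 called lower and 28 adjusted over the list alone (camera adjusted p = 7.6e-11, but 0.111 by that test, 18 of 18 lysates). Translation factors stood at -0.997, with 26 of 32 called lower and 27 adjusted over the list alone (camera adjusted p = 4.21e-08, also 0.111 by that test, 18 of 18 lysates; median -0.64 with an offset of 0.1). Exceptions called higher were the translation repressor ifet-1 (0.96, adjusted p = 2.54e-05, 15 of 18 lysates) and the uncoupling protein ucp-4 (0.72, adjusted p = 9.13e-05, 17 of 18; 0.48, not called, with centred columns).

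**Figure D2:**
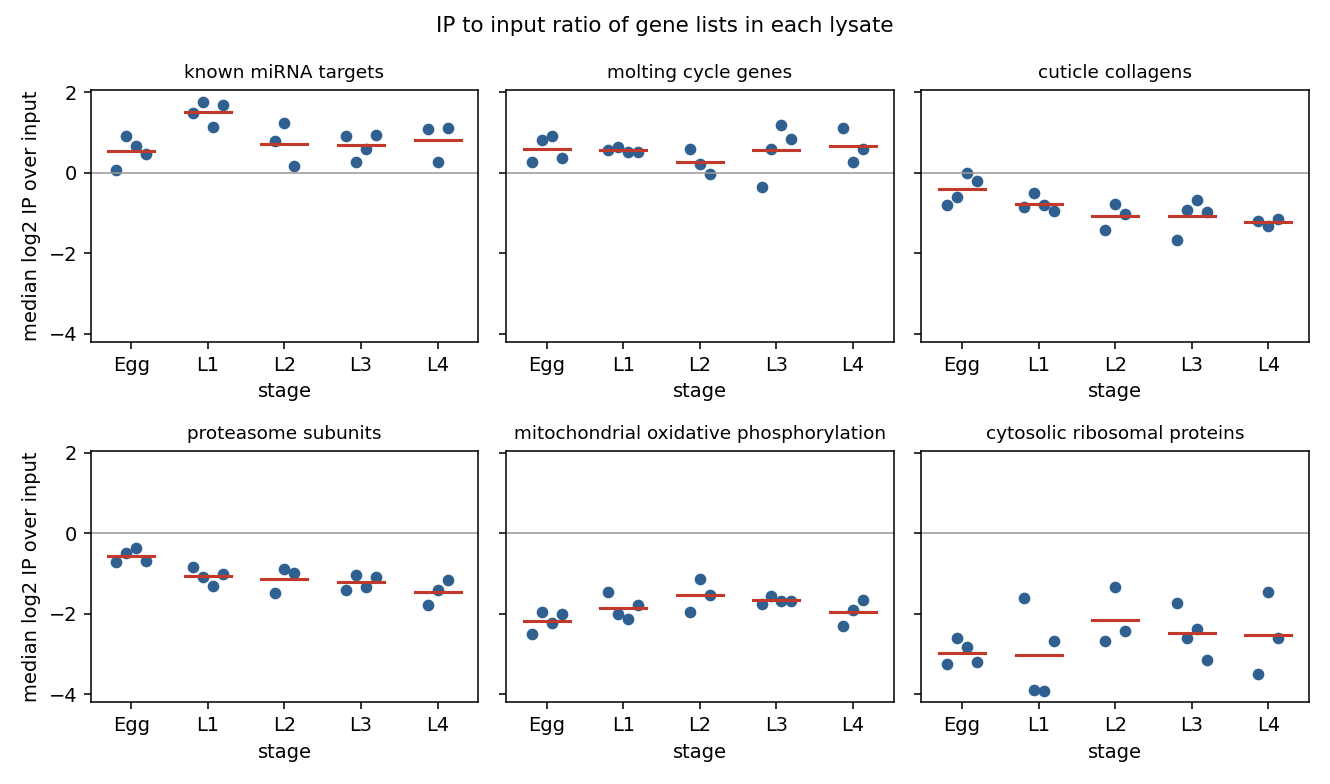
Median log2 IP over input (vertical axis) of 6 gene lists by stage; points are lysates, the red line is the mean of a stage. Ribosomal protein mRNAs lie below 0 and known miRNA targets above 0 in all 18 lysates.

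Further lists were lower in the IP. Cuticle collagens had a median of -0.74, with 67 of 124 called lower and 73 adjusted over the list alone, and were below 0 in 17 of 18 lysates (camera adjusted p = 4.21e-08, but 0.148 with an estimated correlation; median -1.12 over complete genes). Intestinal genes had a median of -0.84 (21 of 38 lower, camera adjusted p = 0.00024, p = 0.117 with an estimated correlation, below 0 in 18 of 18 lysates; -0.56 with an offset of 0.1). The aspartic proteases asp-6 (-2.56) and asp-5 (-2.46) were the lowest of them, while lys-1 was higher in the IP (1.94, adjusted p = 1.08e-08, 18 of 18 lysates). Genes of body wall and pharyngeal muscle had a median of -0.71 (25 of 36 lower, 8 higher, camera adjusted p = 0.00194, p = 0.0853 with an estimated correlation, 18 of 18 lysates). Heat shock proteins and chaperonins had a median of -0.51 (14 of 27 lower, camera adjusted p = 0.0212, p = 0.07 with an estimated correlation, 18 of 18 lysates; -0.28 with an offset of 0.1).

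Molting cycle genes were higher in the IP, with a median of 0.40 (12 of 24 higher, camera adjusted p = 0.00138, but 0.111 with an estimated correlation, above 0 in 16 of 18 lysates; 1.04 over complete genes, 0.85 with lysates of one title spelling). Nuclear hormone receptors had a median of 0.24, with 45 of 161 called higher and 42 adjusted over the list alone (camera adjusted p = 0.00303, p = 0.227 with an estimated correlation, 17 of 18 lysates). Their median ranged from 0.11 with an offset of 0.1 to 0.53 as deposited. nhr-19 (3.38, adjusted p = 3.23e-12) and nhr-20 (3.12, adjusted p = 2.34e-12) were above 0 in 18 of 18 lysates. Ras MAP kinase and EGF signalling genes had a median of 0.31 (8 of 17 higher, camera adjusted p = 0.0239, p = 0.19 with an estimated correlation, 17 of 18 lysates). That call ended with centred columns (0.15) and with lysates of one title spelling (0.20), and the median was 0.20 without Egg replicate 5 or L3 replicate 2, and 0.19 without L4 replicate 1. Wnt signalling genes (median 0.45, 8 of 16 higher, camera adjusted p = 0.0446, 17 of 18 lysates) and homeobox genes (0.16, 16 of 62 higher, camera adjusted p = 0.0446, 15 of 18 lysates) lost their calls with centred columns (0.22 and 0.07). Without L4 replicate 10 the Wnt list was at 0.44 (adjusted p = 0.0762), and without L2 replicate 2 the homeobox list was at 0.12 (adjusted p = 0.0826). With an estimated correlation these 2 lists had p = 0.34 and p = 0.32.

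The other lists were not called by camera at the mean. By median these were vitellogenins (-0.34, 0 of 5 called by limma, camera adjusted p = 0.758), major sperm proteins (-0.43, adjusted p = 0.131), spermatogenesis genes (0.19, adjusted p = 0.226), embryonic specification genes (0.15, adjusted p = 0.123), cell cycle and DNA replication (-0.30, adjusted p = 0.769), histones (-0.25, adjusted p = 0.164, below 0 in 17 of 18 lysates), neuronal genes (-0.19, adjusted p = 0.768), epidermal genes (0.32, adjusted p = 0.107, above 0 in 17 of 18), Notch signalling (0.20, adjusted p = 0.0633, above 0 in 16 of 18) and the ER secretory pathway (-0.20, adjusted p = 0.0593, below 0 in 16 of 18). For germ line and oocyte genes the median (0.09) and the mean (-0.03) differed in sign (adjusted p = 0.629). The same held for insulin signalling (median -0.13, mean 0.07, adjusted p = 0.664), for TGF-beta signalling (median -0.13, mean 0.29, adjusted p = 0.123) and for the miRISC and small RNA machinery (median 0.02, mean -0.01, adjusted p = 0.769). Of the 15 lists called at the mean, 7 had an unadjusted p under 0.05 when the correlation was estimated: known targets (0.00467), heterochronic genes (0.0357), translation factors (0.0192), proteasome subunits (0.0172), oxidative phosphorylation (0.00264), collagens (0.035) and molting cycle genes (0.019). None held after adjustment over the 29 lists, where the lowest was 0.0677.

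Members of the microRNA machinery differed from each other. The mRNA of the Drosha homologue drsh-1 was at 1.90 ± 0.140 (adjusted p = 6.97e-10, above 0 in 18 of 18 lysates). That of ain-1, the paralogue of ain-2, was at 1.25 ± 0.0899 (adjusted p = 4.78e-10, 17 of 18). The mean levels of ain-1 in the IP and the input were close at Egg (1.735 and 1.591). They lay further apart at every larval stage, from 1.838 and 0.4425 at L3 to 2.063 and 0.03 at L4. The Argonaute mRNA alg-1 was at 1.18 ± 0.373 (adjusted p = 0.0148, 13 of 17 lysates), and was not called without L2 replicate 2 (0.95, adjusted p = 0.0757). Its paralogue alg-2 was at 0.51 ± 0.105 (adjusted p = 0.000473, 16 of 18), and was not called with centred columns (0.27, adjusted p = 0.361). The mRNA of the Argonaute ergo-1 was lower, at -1.58 ± 0.263 (adjusted p = 4.95e-05, below 0 in 17 of 18 lysates; -0.74 with an offset of 0.1). That of Dicer, dcr-1, was not called (-0.79, adjusted p = 0.0845). ain-2 itself was not analysed here.

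Each stage was also compared on its own, to find mRNAs held at one time of development. At Egg, 1640 genes and probes were higher in the IP and 1862 lower. At L1 there were 2055 higher and 1547 lower, at L2 985 and 1572, at L3 1414 and 1899, and at L4 1291 and 1757. Of the genes and probes called higher, 41 at Egg, 19 at L1, 14 at L2, 31 at L3 and 26 at L4 had an input not above background. Of those called lower, 30 at Egg, 6 at L1, 139 at L2, 30 at L3 and 14 at L4 had an IP not above background. From 35.61% (L3) to 71.75% (L1) of the genes and probes were above background in every IP of a stage. In every input it was 65.19% (L3) to 76.63% (L4). The counts of calls therefore do not show how many rest on signal near background in some of the arrays. The median of all genes and probes was 0.08 at L1 (0.24 with centred columns), -0.28 at L2 (0.27 as deposited, -0.46 centred, -0.09 with loess), -0.07 at L3 (0.13 as deposited) and -0.15 at L4 (0.09 as deposited). The share of calls that were higher moved with it. At L2 it was 38.5%, against 57.7% as deposited, 21.4% centred and 50.8% with loess. It was 57.1% at L1 (67.2% centred), 46.8% at Egg (36.7% centred), 42.7% at L3 (32.5% centred) and 42.4% at L4 (30.6% centred, 53.1% with loess).

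Here too the highest and lowest genes were ranked only among those with the same sign in every lysate of the stage. D2023.1 was among the 3 highest genes of every stage, from 5.20 at Egg (adjusted p = 1.93e-09) to 6.24 at L4 (adjusted p = 6.81e-10). egl-1 stood at 3.62 in eggs (adjusted p = 5.11e-07, above 0 in 4 of 4 lysates). At L1 egl-46 was highest at 6.12 (adjusted p = 8.98e-12, 4 of 4). At L2 the highest were C08G5.6 at 5.85 (adjusted p = 7.88e-05, above 0 in every lysate with a value) and ZK1236.8 at 5.71 (adjusted p = 6.24e-10, 3 of 3). At L3 nlp-60 was highest at 5.74 (adjusted p = 0.00222), a call that ended without L3 replicate 3 (4.69, adjusted p = 0.0525), and it was 0.77 with an offset of 0.1. hbl-1 was at 5.61 at L3 (adjusted p = 3.17e-11) and at 5.97 at L4 (adjusted p = 9.68e-11). The tubulin gene tba-4 was the lowest at L2, at -5.73 (adjusted p = 4.28e-05, below 0 in every lysate with a value; -1.48 with an offset of 0.1). Major sperm proteins were lower in the IP at L4 (median -1.56, 9 of 31 called lower and 11 adjusted over the list alone, camera adjusted p = 0.000948, p = 0.144 with an estimated correlation), and without L4 replicate 1 this was not called (-1.38, adjusted p = 0.0566). Nuclear hormone receptors at L2 were called higher by camera (adjusted p = 0.0297, p = 0.36 with an estimated correlation) with a median of -0.02 and a mean of 0.10. With an estimated correlation and adjustment over the lists, oxidative phosphorylation genes held at Egg (0.0461), L1 (0.041) and L4 (0.0321), known targets held at L4 (0.0321), and 0 lists held at L2 or L3.

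The IP to input ratio was then compared between consecutive stages. The input is the denominator of this ratio. An IP that followed the input less than fully would therefore shift the ratio without a change of binding. An F test called 422 genes and probes as differing between stages. Between Egg and L1 the ratio rose for 230 and fell for 146. The median of all genes and probes was 0.16 here, and 0.38 with centred columns, and the share that rose was 61.2%, against 71.3% as deposited and 51.2% with loess. With lysates of one title spelling, which leaves 1 L1 lysate, limma made 0 calls, so each call of a gene in this paragraph ended there. F46C5.1 rose most, by 5.04 ± 0.923 (adjusted p = 0.00447, above 0 in 3 of 4 Egg and 4 of 4 L1 lysates; adjusted p = 0.0609 without the replicate block). The ratios of dbd-3 (3.88 ± 0.572, adjusted p = 0.000769) and cpg-8 (3.70 ± 0.385, adjusted p = 6.31e-05) were below 0 in 4 of 4 Egg lysates and above 0 in 4 of 4 L1 lysates. K08D8.5 went the opposite way (-5.12 ± 0.833, adjusted p = 0.00219; -2.04 with an offset of 0.1), above 0 in 3 of 3 Egg lysates with a value and below 0 in 4 of 4 L1 lysates.

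Cell cycle and DNA replication genes rose as a list between Egg and L1, by a median of 0.82 (camera adjusted p = 6.93e-06, but 0.626 with an estimated correlation and adjustment). Over all genes 4 rose and 1 fell, and 13 rose and 1 fell adjusted over the list alone. The Aurora kinase gene air-1 rose by 3.19 ± 0.367 (adjusted p = 0.000152), from below 0 in 4 of 4 Egg lysates to above 0 in 4 of 4 L1 lysates. The cyclin gene cyb-1 rose by 1.99 ± 0.306 (adjusted p = 0.00115; 2.46, adjusted p = 0.0843, with centred columns), with the same change of sign. The ER secretory pathway rose by 0.39 (3 called, 6 adjusted over the list alone, camera adjusted p = 0.000572, p = 0.17 with an estimated correlation; 0.79 centred and 0.69 without Egg replicate 4). The miRISC and small RNA machinery rose by 0.69 (camera adjusted p = 0.0043, p = 0.13 with an estimated correlation; 1.15 centred; not called with lysates of one title spelling, 0.74). Histones rose by 0.43 (camera adjusted p = 0.0151, p = 0.29 with an estimated correlation), a call that ended without Egg replicate 5 (0.38) or L1 replicate 2 (0.34). Collagens fell by 0.42 (camera adjusted p = 7.11e-05, p = 0.07 with an estimated correlation; -0.27 without Egg replicate 4, -0.23 centred). Intestinal genes fell by 0.39 (camera adjusted p = 0.0102, p = 0.18 with an estimated correlation), which was -0.12 and not called without Egg replicate 5. Proteasome subunits (-0.34, camera adjusted p = 0.00239), neuronal genes (-0.23, camera adjusted p = 0.00437) and ribosomal proteins (-0.22, camera adjusted p = 0.0104) turned to 0.06, 0.00 and 0.17 with centred columns, and had p = 0.131, p = 0.24 and p = 0.62 with an estimated correlation. The ribosomal call also ended without Egg replicate 4 (-0.13), L1 replicate 5 (-0.03) or L1 replicate 10 (-0.09), and the value was -0.54 without L1 replicate 2. In total RNA the medians of these lists moved the opposite way from Egg to L1. Examples are cell cycle genes (-1.65), histones (-1.16), intestinal genes (2.70) and ribosomal proteins (1.41). Proteasome subunits were the exception (-0.07). Whether the change of the input gave these shifts of the ratio was not tested.

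Between L1 and L2 the ratio rose for 13 genes and probes and fell for 1. The median of all genes and probes moved from -0.33 with quantile normalization to 0.21 as deposited, -0.78 centred and -0.06 with loess. ZK1236.8 rose by 4.91 ± 0.412 (adjusted p = 2.24e-06), a call made under every alternative run. Its ratio lay between 0.74 and 0.85 in the 4 L1 lysates and between 5.43 and 6.01 in the 3 L2 lysates. Y22D7AL.3 rose by 5.08 ± 0.436 (adjusted p = 2.24e-06), F53A3.1 by 4.56 ± 0.398 (adjusted p = 2.24e-06) and rei-2 by 4.15 ± 0.441 (adjusted p = 4.39e-05). All L2 lysates lay above all L1 lysates for these 3 genes, and their calls ended only with lysates of one title spelling, where the values were 4.40, 3.98 and 3.58. The molting gene mlt-10 rose by 2.23 (adjusted p = 0.000927) and the disulfide isomerase gene pdi-1 by 2.46 (adjusted p = 0.00635), the latter from below 0 in 4 of 4 L1 lysates to above 0 in 3 of 3 L2 lysates. Both lost the call with centred columns (1.32 and 1.51), without the replicate block and with lysates of one title spelling, and pdi-1 also without the variance trend. The pdi-1 call also ended without L2 replicate 1 (2.47, adjusted p = 0.0598) or L2 replicate 2 (2.52, adjusted p = 0.0772). C03D6.1 (4.91, adjusted p = 0.0364), rsp-8, srh-34, T14A8.2 and 3 unnamed probes were the rest of the 13; rsp-8 (4.00), srh-34 (2.79) and T14A8.2 (2.60) are named after their values were seen. The gene that fell was dbd-3 (-3.42, adjusted p = 0.026). The calls of C03D6.1 and dbd-3 ended under 13 alternatives each, among them leaving out L2 replicate 2 (4.75, adjusted p = 0.244, and -3.46, adjusted p = 0.188).

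**Figure D3:**
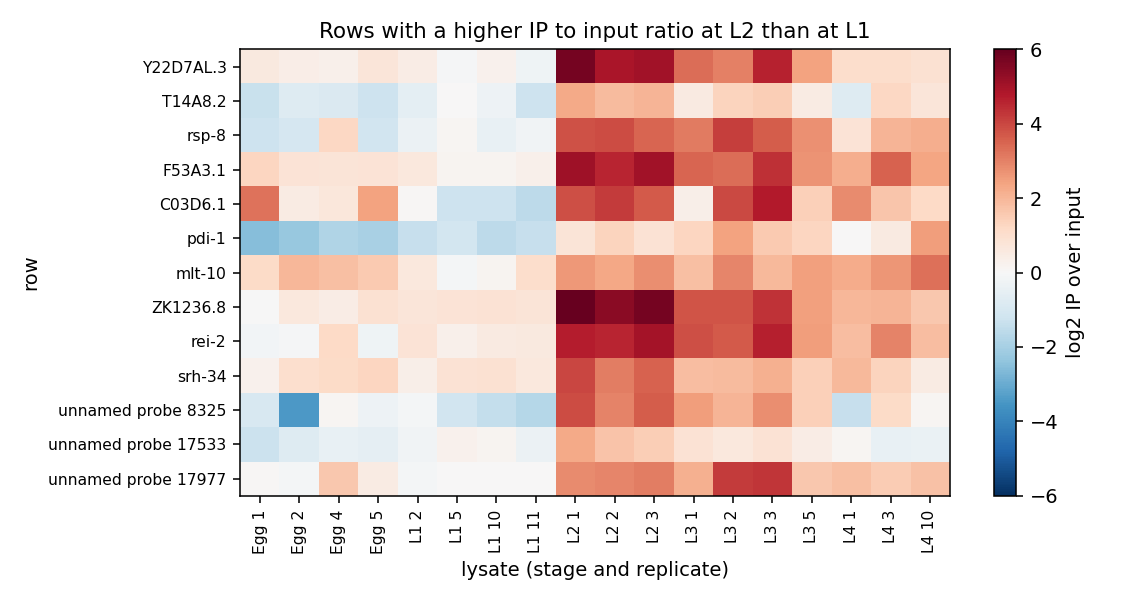
Heat map of log2 IP over input of the 13 genes and probes (vertical axis) whose ratio was higher at L2 than at L1, in the 18 lysates (horizontal axis, by stage). Their median was 0.44 at Egg, -0.02 at L1, 3.48 at L2, 2.62 at L3 and 1.71 at L4.

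As lists, ribosomal proteins rose in ratio from L1 to L2 by a median of 1.02 (camera adjusted p = 5.04e-33, but 0.521 with an estimated correlation and adjustment), with 0 members called by limma. The median was -0.07 with centred columns and -0.32 with lysates of one title spelling. Oxidative phosphorylation genes rose by 0.22 (camera adjusted p = 5.06e-08, also 0.521 by that test) and stood at -0.59 with centred columns. Histones rose by 0.27 (camera adjusted p = 3.35e-05, p = 0.0898 with an estimated correlation) and stood at -0.54 with centred columns. From L2 to L3 limma called 0 genes and probes, with 917 at an unadjusted p under 0.05. All genes and probes had a median of 0.14, against -0.17 as deposited and 0.33 centred. Ribosomal proteins fell by 0.33 (camera adjusted p = 0.00618, p = 0.515 with an estimated correlation), which turned to 0.30 with centred columns and was not called without L2 replicate 2 (-0.12), L3 replicate 2 (-0.02) or L3 replicate 5 (-0.21), but was -0.59 and called without L3 replicate 1. Histones fell by 0.42 (camera adjusted p = 0.000876, p = 0.155 with an estimated correlation), which was not called without L3 replicate 1 (-0.16) or L2 replicate 3 (-0.28). From L3 to L4 limma called 0 genes and probes, with 1077 at an unadjusted p under 0.05. Oxidative phosphorylation genes (-0.31), major sperm proteins (-0.48) and histones (0.24) shifted with the same camera adjusted p of 0.0234. Their p was 0.209, 0.0958 and 0.23 with an estimated correlation. Each of these 3 calls ended under at least 10 alternatives. Without L4 replicate 1 the oxidative phosphorylation genes were at -0.16 and the major sperm proteins at -0.47 (adjusted p = 0.681), without L3 replicate 5 the sperm proteins were at -0.19, and without L3 replicate 1 the histones were at -0.08. Other settings gave larger values, for the sperm proteins -1.49 without L3 replicate 2, -1.21 as deposited and -1.37 centred, and for the histones 0.44 without L3 replicate 3. With an estimated correlation and adjustment over the lists, 0 of the ratio calls between stages held (lowest 0.521). By fry, 2 lists had an adjusted p under 0.05 for the ratio of L1 against Egg and 0 for each later pair of stages.

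The inputs show how total mRNA itself changed between stages. Between Egg and L1, 1754 genes and probes rose and 1803 fell. Intestinal genes rose by a median of 2.70 (24 of 38 called, 26 adjusted over the list alone, camera adjusted p = 5.78e-16). phat-7 rose by 10.2 ± 0.588 (adjusted p = 2.52e-09; 6.03 with an offset of 0.1), the cathepsin gene cpr-1 by 7.92 ± 0.523 (adjusted p = 1.11e-08; 4.78 with the offset) and irg-4 by 7.92 ± 0.612 (adjusted p = 6.01e-08). For each of them all L1 inputs lay above all Egg inputs. The mean Egg levels of phat-7 (-7.53) and cpr-1 (-6.38) were below -5.37, the median of the 3933 genes and probes with the lowest input. The sizes of their rises are therefore uncertain. Ribosomal proteins rose by 1.41 (49 of 59 called, 51 adjusted over the list alone, camera adjusted p = 1.99e-20, but 0.0787 with an estimated correlation and adjustment) and neuronal genes by 1.10 (41 of 106 called, 44 adjusted over the list alone, camera adjusted p = 1.81e-08, but 0.166 by that test; 0.72 with the offset). Cell cycle and DNA replication genes fell by 1.65 (31 of 47 called, 36 adjusted over the list alone, camera adjusted p = 2.53e-15). Germ line and oocyte genes fell by 1.28 (19 of 45 called, 24 adjusted over the list alone, camera adjusted p = 1.81e-08, also 0.166 by that test; -0.74 with the offset). The C-type lectin gene clec-266 fell by 7.41 ± 0.455 (adjusted p = 4.97e-09), with all L1 inputs below all Egg inputs.

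Molting cycle genes (-1.61, camera adjusted p = 2.6e-05, but 0.166 with an estimated correlation and adjustment), histones (-1.16, camera adjusted p = 4.46e-06, p = 0.0535 with an estimated correlation) and epidermal genes (-1.31, camera adjusted p = 0.011, p = 0.1 with an estimated correlation) also fell from Egg to L1. The miRISC and small RNA machinery fell by 0.63 (4 of 25 called, camera adjusted p = 0.011, but 0.0787 with an estimated correlation and adjustment), but not with lysates of one title spelling (-0.50). The same setting ended the calls of known miRNA targets (-0.91, camera adjusted p = 0.0321, p = 0.083 with an estimated correlation) and of the ER secretory pathway (-0.43, camera adjusted p = 0.0107, p = 0.163 with an estimated correlation). Oxidative phosphorylation genes rose by 0.44 (camera adjusted p = 0.011, p = 0.173 with an estimated correlation). Less stable were 4 further lists. Muscle genes rose by 0.38 (camera adjusted p = 0.0321, p = 0.179 with an estimated correlation) but were at 0.26 and not called without Egg replicate 5. Notch signalling fell by 0.89 (camera adjusted p = 0.0303, p = 0.0833 with an estimated correlation) but was at -0.65 and not called without Egg replicate 1. Embryonic specification genes fell by 0.59 (camera adjusted p = 0.0354, p = 0.0536 with an estimated correlation), and this call ended without Egg replicate 4 (-0.71), without L1 replicate 2 (-0.64) and without the dye term (-0.63). TGF-beta signalling rose by 0.96 (camera adjusted p = 0.0468, p = 0.108 with an estimated correlation), a call that ended under 18 alternatives, such as the values as deposited (0.90). With an estimated correlation and adjustment over the lists, only the calls of cell cycle (0.00541) and intestinal genes (0.0203) held.

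From L1 to L2, 285 genes and probes rose in total RNA and 33 fell. The share that rose was 89.6%, against 69.0% as deposited, and the median of all was 0.08, against -0.33 as deposited and 0.52 centred. Molting cycle genes rose by a median of 2.22 (11 of 24 called, 15 adjusted over the list alone, camera adjusted p = 3e-16), the only list call that held with an estimated correlation and adjustment (0.0143). Collagens rose by 0.75 (22 of 124 called, 35 adjusted over the list alone, camera adjusted p = 2.09e-13, but 0.147 by that test; 1.41 centred, 0.34 with an offset of 0.1). col-90 rose by 8.14 ± 0.670 (adjusted p = 3.63e-06) and dpy-8 by 7.44 ± 0.568 (adjusted p = 7.7e-07; 4.73 with the offset), with all L2 inputs above all L1 inputs. The non-coding RNA gene lep-5 rose by 8.04 (adjusted p = 2.11e-07; 5.29 with the offset). The mean L1 levels of col-90 (-5.60), dpy-8 (-5.71) and lep-5 (-5.695) were below -5.37, the median of the 3933 genes and probes with the lowest input. The sizes of their rises are therefore uncertain. Among those that fell, W01A11.7 stood at -3.80 ± 0.609 (adjusted p = 0.00157; -2.02 with the offset; -4.50, adjusted p = 0.0991, with lysates of one title spelling). Proteasome subunits rose by 0.49 (camera adjusted p = 0.000382, but 0.147 with an estimated correlation and adjustment; 1.19 centred), epidermal genes by 0.58 (camera adjusted p = 0.0088, p = 0.0742 with an estimated correlation; 0.16 as deposited, 1.01 centred) and histones by 0.10 (camera adjusted p = 0.0185, p = 0.215 with an estimated correlation; -0.09 as deposited; 0.07 without L2 replicate 1 and 0.23 without L2 replicate 2). Neuronal genes fell by 0.36 (camera adjusted p = 0.000382, p = 0.13 with an estimated correlation; 0.01 centred; -0.21 without L2 replicate 2). The rise of germ line genes (0.69, camera adjusted p = 0.0232, p = 0.691 with an estimated correlation) was not called without L2 replicate 2 (0.55) or L1 replicate 5 (0.60), nor over complete genes (0.23) or with the replicate block across stages (0.34).

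From L2 to L3 limma called 0 genes and probes in total RNA, with 797 at an unadjusted p under 0.05. Here the median of all was -0.19, against 0.07 as deposited and -0.42 centred. Cell cycle and DNA replication genes rose as a list by a median of 0.31 (camera adjusted p = 8.56e-05), but no list call held with an estimated correlation and adjustment, where this list had the lowest value (0.08). Its medians were 0.62 as deposited, 0.13 centred and 0.16 without L3 replicate 2. The calls of germ line genes (0.20), major sperm proteins (0.40), collagens (0.06), proteasome subunits (0.08), neuronal genes (-0.33) and TGF-beta signalling (-0.72) each ended when 1 of several lysates was left out. With an estimated correlation the p values were 0.108, 0.477, 0.199, 0.04, 0.42 and 0.0655. Without L3 replicate 2, germ line genes were at 0.05, major sperm proteins at -0.39, proteasome subunits at -0.01 and TGF-beta signalling at -0.45. Other omissions gave larger values. Collagens were at 0.14 without L3 replicate 2, and the proteasome at 0.22 without L3 replicate 5. Germ line genes were at 0.30 without L2 replicate 3, and major sperm proteins at 0.65 without L3 replicate 1. Without L3 replicate 1 the collagens were at -0.02. With centred columns the medians of the collagens (-0.28) and the proteasome (-0.21) took the other sign. The collagen call held there with its direction against other genes (camera adjusted p = 0.0132), and the proteasome call ended (camera adjusted p = 0.62).

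From L3 to L4, 132 genes and probes rose in total RNA and 6 fell. Over all, the median was -0.02, against 0.13 as deposited and -0.16 centred. Without L4 replicate 3 the count was 29, without L4 replicate 10 it was 355, and without both lysates of lowest IP signal (L3 replicate 1 and L4 replicate 3) it was 4. Sperm and yolk protein mRNAs rose. Major sperm proteins rose by a median of 5.21 (18 of 31 called, 24 adjusted over the list alone, camera adjusted p = 4.47e-43; 2.76 over complete genes, 3.21 with an offset of 0.1), the only list call that held with an estimated correlation and adjustment (0.0427). msp-78 rose by 7.91 ± 1.16 (adjusted p = 0.00207), with 3 of 3 L4 inputs above all L3 inputs; the call ended without the lysates of lowest IP signal (7.16). Spermatogenesis genes rose by 1.36 (4 of 24 called, 9 adjusted over the list alone, camera adjusted p = 9.72e-11, but 0.174 by that test; 0.29 over complete genes), and germ line genes by 0.69 (2 of 45 called, 11 adjusted over the list alone, camera adjusted p = 1.16e-11, but 0.0663 by that test; 1.05 without L4 replicate 10). Vitellogenins, which encode yolk proteins, rose by 4.92 (3 of 5 called, 4 adjusted over the list alone, camera adjusted p = 1.28e-07, but 0.0868 by that test). vit-5 rose by 5.05 ± 0.927 (adjusted p = 0.0103), and its call ended without L4 replicate 1 (4.53, adjusted p = 0.127) or L4 replicate 3 (4.10, adjusted p = 0.147).

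Collagens rose by 0.73 from L3 to L4 (13 of 124 called, 26 adjusted over the list alone, camera adjusted p = 2.61e-10, but 0.163 with an estimated correlation and adjustment; 0.42 centred, 0.29 with lysates of one title spelling). The cuticle collagen gene bli-1 rose by 4.65 ± 0.505 (adjusted p = 0.000299), with 3 of 3 L4 inputs above all L3 inputs, and was called under every alternative run. T19C3.3 was the lowest of the 6 that fell (-3.50 ± 0.409, adjusted p = 0.00052), with 3 of 3 L4 inputs below all L3 inputs. Molting cycle genes fell by 0.43 (0 called by limma, camera adjusted p = 0.00176, but 0.174 with an estimated correlation and adjustment), which was not called without L4 replicate 1 (-0.15) and was -0.89 without L4 replicate 10. Neuronal genes (-0.29), nuclear hormone receptors (-0.23) and homeobox genes (-0.28) were called lower by camera, and each call ended without L4 replicate 3 (-0.22, -0.23 and -0.18). Their p was 0.177, 0.177 and 0.462 with an estimated correlation. Without L4 replicate 1 the medians were -0.13, -0.01 and 0.04, and no receptor or homeobox call was made. In the 3 L4 inputs the median level of major sperm proteins was 2.37, 2.29 and, in replicate 10, -0.59, and that of vitellogenins was 1.38, 2.47 and, in replicate 10, -2.52.

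**Figure D4:**
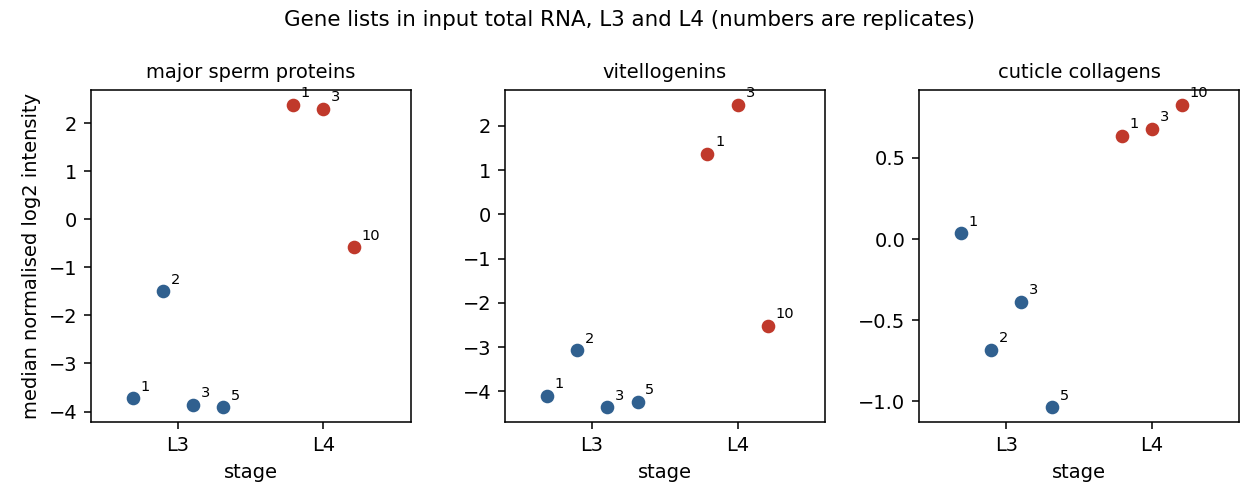
Median level (log2 normalized intensity, vertical axis) of major sperm proteins, vitellogenins and cuticle collagens in total RNA of the L3 and L4 lysates; points are lysates and numbers are their replicates. L4 replicate 10 lies at -0.59 for major sperm proteins and -2.52 for vitellogenins, below the other L4 lysates, but at 0.83 for collagens, above them.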

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

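The tests of input level and of scaling on the ribosomal protein mRNAs, of title spelling and of the change in total RNA on the L2 genes, and each of the tests on L4 replicate 10 were chosen only after the results were seen, while the tests of gene span, of background and of other splits of the samples were chosen before.

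In groups of 4, single samples stood apart from the other 3 in 11 of 186 groups, where chance gives about 1 in 20, or 9.3. The median IP to input ratio of translation factors was -1.89 in Egg replicate 1 (nearest -1.07). In total RNA, TGF-beta signalling was at -3.21 in Egg replicate 5 (nearest -2.41) and at -1.78 in L1 replicate 11 (nearest -1.37), and the ER secretory pathway was at 1.58 in Egg replicate 4 (nearest 2.15). L1 replicate 10 was low in the ratio of histones, -0.60 (nearest -0.43), and in total RNA of oxidative phosphorylation genes, 1.31 (nearest 1.46). In total RNA of L1 replicate 2, 16.5% of the spots were at or below 0 (nearest 11.7%). L3 replicate 1 was low in the ratio of the miRISC machinery, -0.82 (nearest 0.14), and of TGF-beta signalling, -0.83 (nearest 0.42). L3 replicate 2 was high in total RNA of major sperm proteins, -1.50 (nearest -3.73), and low in their ratio, -1.72 (nearest 0.03).

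The IP to input ratio differed between stages for 422 genes and probes. It was higher at L1 than at Egg for 230 and lower for 146, and it was higher at L2 than at L1 for 13 and lower for 1. As lists, cell cycle and DNA replication rose by 0.82 from Egg to L1, and ribosomal proteins by 1.02 and oxidative phosphorylation by 0.22 from L1 to L2. With an estimated correlation and adjustment none of these 3 calls held (0.626, 0.521 and 0.521), and with centred columns the last 2 were at -0.07 and -0.59. Among 6417 genes and probes with too few values to be tested, 105 were above background in every IP at Egg, 255 at L1, 55 at L2, 15 at L3 and 96 at L4.

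Other splits of the samples show what structure other than the named groups can give. At the mean of the 5 stages, the real split gave 6960 calls. The highest of the other 99 splits, which swap IP and input in some lysates, gave 2901 (1 of 100). The real split also gave the most calls for any difference between stages (422 against 15, 1 of 100). For the ratio of L1 against Egg (376 against 0) and of L2 against L1 (14 against 0), the real split gave the most calls of 35. The same held for total RNA of L1 against Egg (3557 against 3) and of L2 against L1 (318 against 41). Shares of 1 of 100 and 1 of 35 are the lowest that 100 and 35 splits can give. They were not adjusted over the comparisons, so chance is unlikely for each taken alone but is not excluded. Within a stage the real split parts every IP from its input, and it was set beside the splits that part as many pairs, which swap IP and input in some lysates. These are too few for a share under 0.05: 8 at Egg (3502 against 281), 8 at L1 (3602 against 2), 4 at L2 (2557 against 2), 8 at L3 (3313 against 166) and 4 at L4 (3048 against 23), where the pairing is the replicate block (1678 calls at Egg without it). The splits that part fewer pairs gave up to 1896 at Egg, 1127 at L1, 144 at L2, 1556 at L3 and 912 at L4.

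Where the real count was 0 every split gives as many, 35 of 35, so the splits say nothing on chance there: the ratio of L3 against L2 (highest other 6), the ratio of L4 against L3 (174) and total RNA of L3 against L2 (2). For total RNA of L4 against L3, 2 of 35 splits gave as many as the real 138, so chance was not excluded there. The split that put L4 replicate 1 with L3 replicates 2 and 3 gave 558, several times the real count. This points to a structure among these samples. The inputs put together by that split had the highest mean signal, 1795 to 2558 steps, against 593.5 to 983.7 in the other L3 and L4 inputs. Their noise was also higher, 12.93 to 16.58 steps against 3.528 to 4.155. That split thus also parts the inputs by scan brightness. Whether brightness gave the 558 calls was not tested. The split with 174 calls put together L4 replicate 3 and L3 replicates 1 and 3, and L4 replicate 3 and L3 replicate 1 are the 2 lysates of lowest IP signal.

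The first pattern weighed is the low IP to input ratio of ribosomal protein mRNAs, a median of -2.52 with quartiles of -2.67 and -2.30. A flattened signal of the brightest mRNAs is argued against by 175 other genes of like input level (median input 4.3, against 4.66), whose median ratio was 0.0286 with quartiles of -1.03 and 0.26. Gene span is argued against as the whole cause by 278 other genes of like span, whose median was -0.32 with quartiles of -1.07 and 0.18, although 106 of them were lower in the IP and 34 higher. The scaling of the columns is argued against because the difference of the list from the median of all genes and probes was -2.43 or lower under each of 5 scalings. RNA that sticks to the beads without AIN-2 was not tested and stays open, as does mRNA length, which gene span does not give, so weaker holding of these mRNAs by the silencing complex is only a hypothesis.

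The second pattern is the 13 genes and probes whose ratio rose from L1 (median -0.02) to L2 (3.48), and stage is the biological difference in the design. An array batch marked by the title spelling is argued against by the 4 Egg and L1 lysates that share the spelling of the L2 lysates, where the highest median was 0.69. A fall of the input is argued against by its median change in total RNA, 0.67, with quartiles of 0.05 and 0.89 and 0 called by limma. An input near background is argued against for 12 of the 13, which were above background in every L1 and L2 input. A change of binding with stage is a hypothesis only, since it was found and tested on the same data.

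The third pattern is L4 replicate 10, with low major sperm protein (-0.59) and vitellogenin (-2.52) mRNA in total RNA. A weak array is argued against, since 71.4% of its input spots were above background, against 63.9% and 66.0% in the other L4 inputs. An L3 sample under an L4 title stays open, because over 355 genes and probes its median position was 0.31 (quartiles 0.13 and 0.47) from the L3 mean at 0 to the other L4 inputs at 1, and held-out L3 inputs reached from -0.03 to 0.28, while its germ line genes (-2.02) lay among the L3 inputs (-2.88 to -1.74). Against it stand the collagens (0.83, with the L3 inputs at most at 0.04). For genes such as bli-1, T19C3.3 and msp-78 every L4 input lay outside all L3 inputs. They cannot decide this, because they were chosen as calls of a fit that included this lysate. Of the genes called without it, 61.9% to 73.2% lay beyond 3 L3 inputs towards L4 in this lysate, but 19.3% to 64.2% did so in the L3 input held out. Younger L4 animals also stay open, because the position of 18 collagens (0.39) minus that of 26 sperm and yolk genes (0.48) was -0.10, and with 1 such lysate these 2 explanations cannot be told apart. Replicate 10 was also the only L4 input in Cy3 and the only one titled "Tot". The positions carry no dye correction, and neither dye nor title spelling was weighed for this pattern. The highest held-out L3 position (0.28) and share (64.2%) were those of L3 replicate 2, the only L3 input in Cy3. The other held-out L3 inputs had positions from -0.03 to -0.01.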

How the results depend on the processing

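The floor, the offset, the 2 settings on the title spelling and the omission of the 2 lysates of lowest IP signal were chosen after the data were seen, and the other alternatives before. Signal over background limits what the ratios of dim mRNAs can show: the offset pulls them towards 0 and the floor cuts them off. The counts of the IP against the input at the mean of the 5 stages stayed within 1.5 times 6960 under every alternative but one, and at least 4383 of those calls were shared. Of the shared calls, 1 had the opposite sign with the brightest probe of a gene and 0 under the others. With no dye term and with the brightest probe, all 15 counts stayed within 1.5 times. A list is said to shift the other way where its direction against all other genes changed, and the value given is its median, which can keep its sign. Where no reason is given below, the cause was not tested.

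With the values as deposited, the count of the ratio of L1 against Egg was 717, of L2 against L1 31, of L3 against L2 2 and of any difference between stages 769. Ribosomal proteins, not called before, shifted the other way against all other genes in total RNA of L2 against L1 (0.11, from 0.06) and of L3 against L2 (-0.24, from -0.08), with medians of unchanged sign. With centred columns the counts were 46 for the ratio of L1 against Egg, 6 for L2 against L1 and 92 for any difference between stages. Centred, ribosomal proteins did so in the same 2 comparisons (0.96 and -0.72), again with medians of unchanged sign, as did the ER secretory pathway in the ratio of L2 against L1 (-1.15, from -0.25). The medians of ribosomal proteins in the ratio of L3 against L2 (0.30) and of oxidative phosphorylation in that of L2 against L1 (-0.59) took the other sign. With loess the ratio of L2 against L1 gave 26 calls.

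Without the replicate block, which drops the pairing of IP and input, the counts were 1678 at Egg, 1887 at L1, 889 at L2, 1549 at L3 and 1252 at L4, with 67 for the ratio of L1 against Egg, 8 for L2 against L1 and 61 for any difference. A random lysate block gave 22 for the ratio of L2 against L1. With the replicate number as a replicate block across stages in place of the dye, the ratio gave 189 for L1 against Egg, 9 for L2 against L1 and 215 for any difference, total RNA gave 158 for L2 against L1 and 1 for L3 against L2, and major sperm proteins turned to -0.29 in total RNA of L2 against L1. Without the dimmest 0.25 of the genes, total RNA of L4 against L3 gave 72 calls, and over complete genes 40, where fewer genes were tested. Without the variance trend the ratio gave 187 for L1 against Egg and 146 for any difference. Each stage alone gave 5970 at L1, 1588 at L3 and 1278 at L4. With the brightest probe, mab-10 turned to 1.04 at L2 and T04B8.5 to 0.0712 in the ratio of L1 against Egg.

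With the floor, the ratio of L2 against L1 gave 22 calls and total RNA of L4 against L3 338. col-81 turned to -0.19 at the mean, and T04B8.5 to 0.37 at L1 and to 1.10 in the ratio of L1 against Egg. With the offset, the ratio gave 1076 calls for L1 against Egg, 45 for L2 against L1, 10 for L4 against L3 and 1216 for any difference, and total RNA gave 1 for L3 against L2 and 514 for L4 against L3. col-81 turned to -0.23 at the mean, ceh-16 to -0.0434 at L4 and T04B8.5 to 0.19 in the ratio of L1 against Egg. With the title spelling as a term, total RNA of L3 against L2 gave 1 call, ribosomal proteins turned to 0.0688 in the ratio of L1 against Egg and major sperm proteins to -0.43 in total RNA of L2 against L1.

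With lysates of one title spelling 12 lysates were left, 1 of them L1. The counts were 1871 at Egg, 192 at L1, 1354 at L2, 1892 at L3, 1012 at L4 and 4431 at the mean. The ratio gave 0 calls in limma for L1 against Egg (550 at an unadjusted p under 0.05), 2 for L2 against L1 and 33 for any difference, and total RNA gave 705 for L1 against Egg and 86 for L2 against L1. Fewer lysates belong to this setting by construction, and the lone L1 lysate is assumed to vary like the others. Ribosomal proteins turned to 1.03 in the ratio of L1 against Egg and to -0.32 in that of L2 against L1. Without the 2 lysates of lowest IP signal the ratio gave 771 for L1 against Egg, 34 for L2 against L1 and 691 for any difference, and total RNA gave 4 for L4 against L3.

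Leaving out 1 lysate at a time gave from 2105 (without Egg replicate 2) to 4017 calls at Egg, 2478 (L1 replicate 10) to 4054 at L1, 1086 (L2 replicate 1) to 3077 at L2, 2179 (L3 replicate 2) to 3535 at L3, 2183 (L4 replicate 3) to 3539 at L4 and 6256 (L2 replicate 2) to 7266 at the mean. The ratio gave 169 (L1 replicate 5) to 505 for L1 against Egg, 7 (L2 replicate 1) to 21 for L2 against L1, 0 to 1 for L3 against L2 and for L4 against L3 (1 without L3 replicate 2 and without L4 replicate 1) and 203 (Egg replicate 2) to 577 for any difference. Total RNA gave 2608 (L1 replicate 10) to 3848 for L1 against Egg, 155 (L2 replicate 3) to 401 for L2 against L1, 0 to 1 (L3 replicate 5) for L3 against L2, and 29 (L4 replicate 3) to 355 (L4 replicate 10) for L4 against L3. Among the named genes, 15990 of these values kept their direction and side of the threshold, 957 lost a call and 9 gained one. Among the lists 7114 kept both, 111 lost a call, 81 gained one and 2 shifted the other way: ribosomal proteins in the ratio of L4 against L3 without L4 replicate 1 (0.29, with -0.86 as the lowest, without L4 replicate 3) and major sperm proteins in total RNA of L3 against L2 without L3 replicate 2 (-0.39, with 0.65 as the highest, without L3 replicate 1). The median alone took the other sign in 258 of the 7308 values, 15 of them of 7 lists called with all lysates, such as homeobox genes in total RNA of L4 against L3 without L4 replicate 1 (0.04).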

Other observations

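Longer genes were more often enriched in the IP. Among the named genes with a span in the annotation, the share called higher at the mean of the 5 stages was 12.3% in the 3012 with the shortest gene span (median 932 bases) and 26.4% in the 3001 with the longest (median 5859 bases). The share called lower went from 37% in the former to 18.2% in the latter. The span is that of the gene with its introns, and the length of the mRNA or of its 3' untranslated region was not analysed here.

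The share of calls also followed the input level, which bears on how many calls could be made. Of the 3933 genes and probes with the lowest input, 10.0% were called higher and 2.01% lower, and of the 3933 with the highest input 29.7% were higher and 44.5% lower. Both comparisons were made after the data were seen, and the genes are not independent replicates.

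The dye term of the IP fit called 18 genes and probes higher and 40 lower when the IP carried Cy5.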
